A study of Nothobranchius furzeri with 10 samples.

How the data were processed

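Total RNA from killifish brain was made into sequencing libraries with a TruSeq RNA kit, version 2, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4, which convert base calls to reads, align reads and count them over genes. The genome build, the gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Genes that overlap, or that share reads with near-identical copies, are therefore uncertain.

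The authors deposited a table of read counts per gene, with 1 column per library and 26739 genes, as whole numbers without normalization. They also deposited a table of RPKM values (reads scaled to gene length and library size) for the same libraries and genes. The deposited RPKM values were compared with the counts in 8908 genes with a mean count above 500. The gene length implied by count and RPKM was constant over the 10 libraries only if the library totals were taken as running down the genes of the table in turn, so that 10% of the values had been divided by the total of their own library. The deposited RPKM values were thus not comparable between libraries, and the counts carried every main comparison.

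Samples were grouped by the perturbation label, 5 as miR-101a and 5 as scrambled. Replicate numbers 1 to 5 follow the order of the records and only name libraries. The labels do not say that the libraries came from separate fish, so p-values measure the spread between these samples, which may be technical. The labels give no sequencing batch or date. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 9.93 to 40.81 between pairs over genes with at least 20 reads, so each library counted once.

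Gene counts were analysed in R 4.3.3 with edgeR 4.0.16. Of 22808 genes with any read, filterByExpr kept 19094, which held 99.95% of the counts. TMM factors lay between 0.991 and 1.005. The common dispersion was 0.032, a biological coefficient of variation of 17.9%. Robust quasi-likelihood fits (glmQLFit and glmQLFTest, with the default quasi-dispersion method of that version) used all 10 libraries and no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05 and no minimum fold. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Group means in CPM (counts scaled to library size) used TMM-scaled library sizes. Library totals, genes detected, the share of the 10 most abundant genes, the median Spearman correlation with the other libraries and the scores on 2 principal components were compared between groups with two-sided exact permutation tests over 252 regroupings, adjusted over these 6 measures. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

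Counts drawn from the libraries' own means, sizes and dispersions, with 200 of the genes changed by known folds, were used to test the fit on simulated data of 5 against 5 libraries. Among 18971 genes tested there, the fit called 10% of 50 genes changed 1.25-fold and 40% of 50 changed 1.5-fold. It called 70% of 50 changed 2-fold and 84% of 50 changed 3-fold. Over all fold sizes simulated there were 8 false calls beside 102 true ones. The simulation did not include differences between libraries that affect many genes together. Its 200 changed genes also ease the Benjamini-Hochberg cutoff, so these shares may overstate power in the real fit.

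The tests, the sample groups and most of the alternatives were fixed before the data were examined, as were 42 gene lists and a rule for the genes given by name. That rule took genes with a symbol, up to 12 per direction by smallest p among those past the threshold, or the 10 with the smallest unadjusted p if fewer than 5 passed. A reference table of 38438 genes from another assembly matched 0 of the identifiers, so the rule gave no gene, the 42 lists had no members, and the 2 genes per direction with the smallest p are given by identifier instead, a choice made after the missing symbols were seen. A planned test of genes with miR-101 sites in their 3' untranslated regions was not run because no genome or annotation was used here.

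Alternatives were other size factors (RLE and upper quartile), no filter or a filter of at least 1 CPM in 5 libraries, an adjusted p of 0.1, DESeq2 1.42.0, limma-voom with quality weights (limma 3.58.1), 1 surrogate variable (sva 3.50.0), limma-trend on log2 of the deposited RPKM plus 1 or plus 0.1 with a minimum of 0.5 in 5 libraries or no minimum, and leaving out each library. Others were added after the data had been seen: RPKM recomputed with each library's own total, removal of a gene length trend, leaving out miR-101a replicates 1 and 5 together, leaving out miR-101a replicate 4 and scrambled replicate 1 together, every choice of 3 libraries from each group, the library of each side nearest the other side on the first component left out in each of the 100 splits, the 6 libraries whose title numbers (21, 22 and 23) occur in both groups with and without that number as a block, and edgeR without robust estimation or with its newer quasi-dispersion method, principal components without genes near 0 in some libraries, and leaving out each library in the comparisons of components and library composition. Genes were called present in some libraries and near 0 in others where the sorted values of log2(CPM + 0.05) had a gap of at least 2.5 and every value above the gap was at least 1 CPM, thresholds set in a first look at the data. CPM in this step used library totals without TMM factors.

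The fit was repeated on 100 of the 126 ways to split the 10 libraries into 5 and 5 with edgeR, and on 50 of these with DESeq2, the real split included.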

Results

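Messenger RNA was measured by RNA sequencing in 10 brain samples of male turquoise killifish (Nothobranchius furzeri, strain MZM-0410p) aged 22 weeks. This fish is an annual species kept in laboratories to study ageing because its life is short. Per the perturbation labels, 5 samples came from fish given synthetic miR-101a at 100 pmol and 5 from fish given a scrambled control. MicroRNAs such as miR-101a are short RNAs that lower the stability and translation of messenger RNAs with matching sites. The design text of the series instead calls the agent an antagomiR, which is an inhibitor of a microRNA. Whether the agent added or blocked miR-101a was therefore left open, and no direction was assumed. The groups are called miR-101a and scrambled, and log2 fold changes are miR-101a minus scrambled.

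Reads counted to genes ranged from 21708509 to 27086488 per library in the miR-101a group and from 19598030 to 25598103 in the scrambled group, a difference in means within the spread of replicates (two-sided exact permutation test, p = 0.698, adjusted p = 0.897 over 6 measures). Genes with at least 1 read numbered 21550 to 21657 in the miR-101a libraries and 21460 to 21742 in the scrambled libraries (exact permutation p = 0.849, adjusted p = 0.897). The 10 most abundant genes took 3.62% ± 0.257 (SD, n = 5) of the counts in the miR-101a group and 3.44% ± 0.114 (SD, n = 5) in the scrambled group, which did not differ by the same exact test (p = 0.19, adjusted p = 0.57).

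The comparison of the 2 groups asked which brain transcripts differed after the miR-101a agent. Among 19094 genes tested with edgeR's quasi-likelihood test, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.304. At an unadjusted p below 0.05 there were 935 genes, of which 471 were higher and 464 lower in the miR-101a group, against 955 if p-values were uniform. The next 7 bins of 0.05 in p held 1001 to 1155 genes each, above that number. Without miR-101a replicate 4 the count at an unadjusted p below 0.05 was 1852. DESeq2 called 15 genes at an adjusted p of 0.05, 11 higher and 4 lower, and limma-voom with sample quality weights called 0. The edgeR adjusted p of those 15 genes ran from 0.304 to 0.88. Leaving out any single library gave 0 as well. With miR-101a replicate 4 and scrambled replicate 1 both left out, a pair chosen after the data had been seen because each lay nearest the other group on the first principal component, edgeR called 484 genes at an adjusted p of 0.05, of which 14 were higher in the miR-101a group. That choice depends on the outcome. Treated in the same way, 16 of 100 splits of the libraries, the real one included, gave as many. That share is no test of chance. The rule turns splits 1 exchange away from the split into low and high scores on that component back into it.

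Differences between the group means were small across the brain transcriptome. The median size of the log2 fold change was 0.078, 95% of genes lay below 0.49, and the median standard error was 0.1. Of 19087 genes with a standard error, 17316 (90.7%) had a 95% interval of the log2 fold change, without adjustment for the number of genes, that lay within a 2-fold change in either direction. In 14472 genes (75.8%) the interval lay within a 1.5-fold change. For the remaining genes a difference of that size was not excluded. Of the 172 genes with a log2 fold change beyond 1 in size, the smallest unadjusted edgeR p was 0.00053, and none of them passed the adjustment. The libraries of the 2 groups did not overlap in 125 genes, 62 higher and 63 lower in the miR-101a group, which was 0.65% of the genes tested against 0.79% by chance (152 genes).

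**Figure D1:**
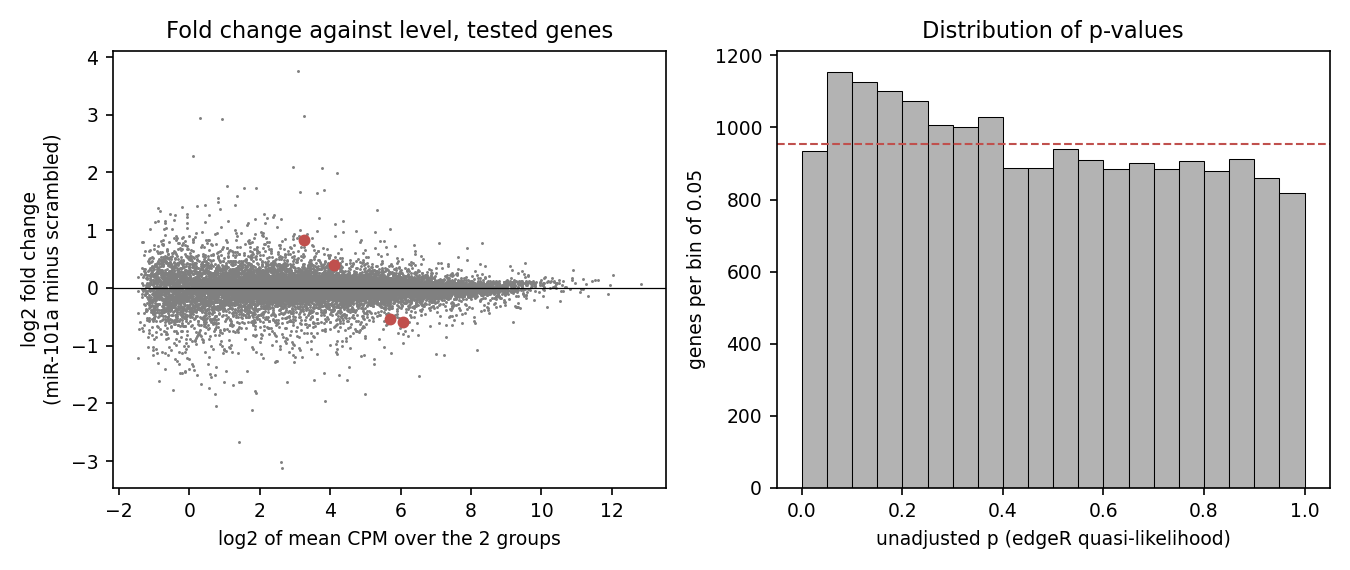
Left, log2 fold change (miR-101a minus scrambled) against the log2 of the mean CPM for the 19094 genes tested, each point a gene, with the 4 genes given by identifier in red. Right, number of genes per bin of unadjusted edgeR p, with the count under uniform p-values as a dashed line; the bin nearest 0 held 935 genes, below the 955 of the line, and the next 7 bins lay above it.

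CPM here are counts scaled to the size of each library. The deposited tables name genes only by identifiers that they do not pair with symbols, so the 2 genes with the smallest p in each direction are given by identifier, and none of them passed the adjustment in edgeR. Nfu_g_1_020914 was measured at 12.2 ± 1.59 CPM (SD, n = 5) in the miR-101a group and 6.86 ± 0.863 CPM (SD, n = 5) in the scrambled group, a log2 fold change of 0.83 with a standard error of 0.11 and an edgeR adjusted p of 0.304. Nfu_g_1_010218 stood at 19.5 ± 1.69 CPM against 14.7 ± 0.477 CPM (SD, n = 5 each), a log2 fold change of 0.405 with a standard error of 0.068 and an edgeR adjusted p of 0.553. On the lower side, Nfu_g_1_003402 was measured at 42.8 ± 4.43 CPM against 62.0 ± 6.12 CPM (SD, n = 5 each), a log2 fold change of -0.535 with a standard error of 0.085 and an edgeR adjusted p of 0.553. Nfu_g_1_000965 stood at 53.2 ± 5.57 CPM against 80.4 ± 12.1 CPM (SD, n = 5 each), a log2 fold change of -0.595 with a standard error of 0.106 and an edgeR adjusted p of 0.565. In each of these 4 genes the 5 libraries of one group lay outside the range of the other. All 4 were among the 15 genes that DESeq2 called, with DESeq2 adjusted p-values of 2.05e-06, 0.0013, 0.000111 and 0.000764 in the same order. In DESeq2, 17 of 50 splits of the libraries, the real one included, gave at least 15 genes, so chance is not excluded for these calls.

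Spearman correlations of log2 CPM across genes between pairs of libraries ran from 0.975 to 0.992, with a median of 0.987 within groups and 0.9861 between groups. The first principal component of the 1000 most variable genes held 26.5% of their variance and the second 16.0%. Scores on the first component averaged -10.4 ± 19.9 (SD, n = 5) in the miR-101a group and 10.4 ± 8.84 (SD, n = 5) in the scrambled group, and the groups overlapped (two-sided exact permutation test over 252 regroupings, p = 0.119, adjusted p = 0.57). The design could reach an exact p of 0.0079. Without miR-101a replicate 4, the library of that group on the scrambled side, the exact p for the first component was 0.024, before any adjustment. That library was singled out by the same scores, and without any other single library the exact p was 0.056 to 0.198. The second component did not separate the groups either (exact permutation p = 0.897, adjusted p = 0.897).

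**Figure D2:**
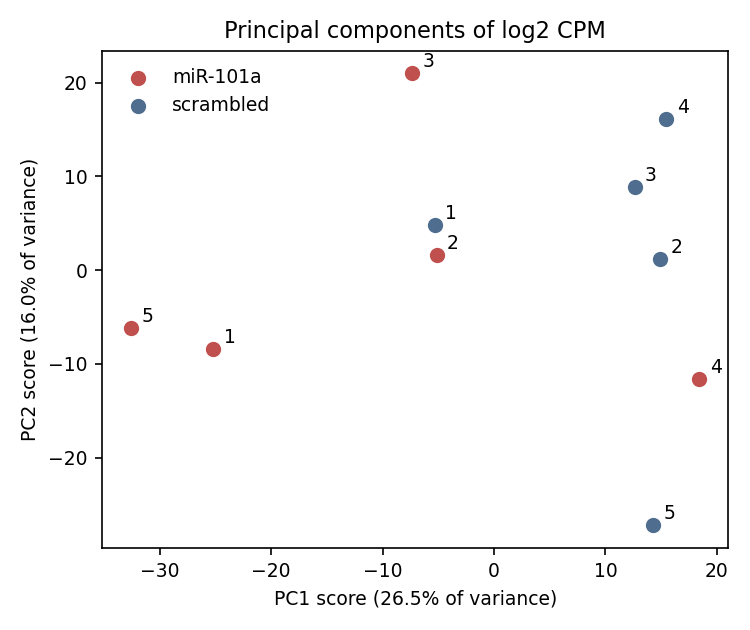
Scores of the 10 libraries on the first (horizontal, 26.5% of variance) and second (vertical, 16.0%) principal component of log2 CPM, with miR-101a libraries in red, scrambled libraries in blue and replicate numbers beside the points. Replicates 5 and 1 of miR-101a lie farthest left at -32.57 and -25.19, while miR-101a replicate 4 lies at 18.42, to the right of all 5 scrambled libraries (-5.33 to 15.45).

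A search added after the data had been seen found 115 genes that were present in some brain libraries and near 0 in the others, and in 0 of them did the libraries near 0 form one treatment group. Only the 13 genes near 0 in 5 libraries could have matched a group, and 11 of them shared 1 pattern. Near 0 means below a gap of at least 2.5 in log2, so single values there can reach a few CPM. Sets of at least 5 genes with the same libraries near 0 numbered 8 and held 71 of the 115 genes. A set of 12 genes was near 0 in miR-101a replicates 1 and 5, where its median was 0.319 and 0.37 CPM, and had medians of 10.07 to 18.77 CPM in the other 8 libraries. The most abundant gene of that set was at 1.73 to 4.36 CPM in those 2 libraries and at 503.5 to 1256 CPM in the other 8. A set of 11 genes was near 0 in miR-101a replicates 2, 3 and 5 and scrambled replicates 3 and 4, with medians of 0.141 to 0.234 CPM, and had medians of 3.65 to 8.11 CPM in the other 5 libraries. A set of 7 genes was present in miR-101a replicates 4 and 5 and scrambled replicate 3, with medians of 5.44 to 24.9 CPM, and had medians of at most 0.141 CPM in the other 7 libraries. The other 5 sets each set a single library apart. Of these, 15 genes were higher in miR-101a replicate 5 than elsewhere (median 5.99 CPM, against at most 0.354 CPM), 9 in miR-101a replicate 1 (7.71 against at most 0.51 CPM), 6 in scrambled replicate 4 (5.22 against at most 0.462 CPM) and 5 in scrambled replicate 5 (17.4 against at most 1.81 CPM), and 6 were near 0 in miR-101a replicate 1 alone (0.0684 CPM, against 4.46 to 9.74 CPM elsewhere). These sets were chosen by their values, so no test between the libraries was made.

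**Figure D3:**
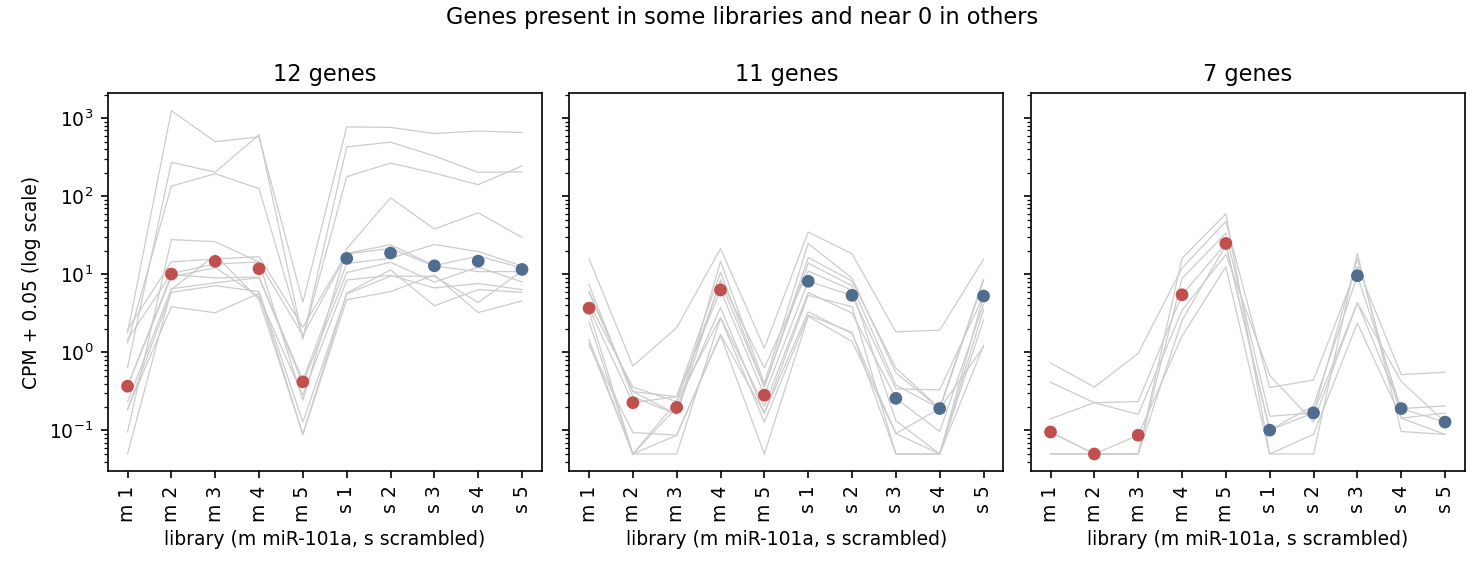
CPM plus 0.05, on a log scale, in each of the 10 libraries for the sets of 12, 11 and 7 genes, with a grey line per gene and a point for the median of the set, red for miR-101a and blue for scrambled libraries. The libraries near 0 come from the miR-101a group alone in the set of 12 genes and from both groups in the sets of 11 and 7 genes.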

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

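Each of 10 measures was examined within both groups for a library far from the others, as a gap to its neighbour above 0.71 of the group's range. For independent, normally distributed values chance gives such a gap in about 1 of 20 groups. Among the 20 groups examined there were 3. The measures share the same libraries and include the CPM of the genes given by identifier, which were picked by p. The number of gaps therefore has no exact chance value to be set against.

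The score of scrambled replicate 1 on the first principal component was -5.33, while the other 4 scrambled libraries lay between 12.61 and 15.45. Its score was close to that of miR-101a replicate 2, at -5.16.

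The median Spearman correlation of miR-101a replicate 5 with the other libraries was 0.9778, against 0.9857 to 0.9883 for the other miR-101a libraries. That of scrambled replicate 5 was 0.9859, against 0.9878 to 0.9883 for the other scrambled libraries. Leaving out miR-101a replicate 5 gave 0 genes at an adjusted p of 0.05 in edgeR, as did leaving out scrambled replicate 5.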

How the results depend on the processing

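Settings chosen only after the data had been seen were RPKM with each library's own total, the removed length trend, every fit that left out several libraries, the block on title numbers, both changes to the edgeR dispersions, the components without genes near 0, and leaving out single libraries for components and composition.

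Of 29 alternatives for the number of genes past the threshold, 25 gave 0, as edgeR on all libraries did, including limma-voom and leaving out each library in turn. DESeq2 gave 15 genes, 14 of them among the 20 with the smallest edgeR p; the cause was not tested. Leaving out miR-101a replicate 4 and scrambled replicate 1 together gave 484 genes. Among the 100 choices of 3 libraries from each group, the 16 with neither of these 2 libraries gave 171 to 481 genes, and the other choices gave at most 5. This pair was chosen by its place on the first component. With the libraries nearest the other side left out alike, 16 of 100 splits gave at least 484 genes, up to 737. That rule turns splits 1 exchange away from the split into low and high scores on this component back into it. The share follows largely from the rule and does not test chance, which is not excluded. Title numbers 21, 22 and 23 occur in both groups, and no label says that they pair libraries. Deviations of same-numbered libraries from their group means correlated across genes at -0.06, 0.04 and -0.22, too coarse to exclude pairing. Their 6 libraries, which include neither of those 2, gave 332 genes with the number as a replicate block and 364 with no replicate block. Of the 10 splits of these 6 libraries, 1 gave as many as 364, the real one, and another gave at most 1, but 10 splits are too few for a share under 0.05.

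When single libraries were left out, the number of genes at an unadjusted p below 0.05 was 629 to 1852, against 935 with all libraries, the highest without miR-101a replicate 4, and the smallest adjusted p was 0.0866, without miR-101a replicate 5. The deposited RPKM, with their misplaced totals, gave 313 genes at that unadjusted p and RPKM with own totals 956. The 4 genes given by identifier, picked by p, kept their sign in 108 of 108 alternatives, which tests little. The 13 past the threshold came from DESeq2 and fits without miR-101a replicate 4 and scrambled replicate 1. The exact p of the first component was 0.119 and ran from 0.024 without miR-101a replicate 4 to 0.198 without miR-101a replicate 5, and the total count gave no exact p below 0.484. The 42 gene lists and the miR-101 site sets, with their alternatives, were not run, for lack of symbols and a genome. Simulated 2-fold changes were called in 70% of genes and 1.5-fold changes in 40%. These shares may be too high here, so changes of these sizes can be missed.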

Other observations

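The tests in this part were chosen after the results had been seen, except the edgeR split count of genes past the threshold, which was set before the data were examined and whose reading was corrected with the data at hand, before any other split was fitted. The split count for unadjusted p was added once the real count was known but before those of other splits, and that for DESeq2 once its real count and the edgeR split counts were known.

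Genes present in some libraries and near 0 in others formed sets that followed neither treatment group. The libraries near 0 were exactly one group in 0.0% of the 115 genes, which restates how the sets look and is no separate test of a switch by the treatment. Only 13 of the 115 genes were near 0 in 5 libraries and so could have matched a group. If a set reflects 1 cell population or tissue part sampled in varying amount, its genes should also vary together where they are present. In the set of 11 genes the median pairwise correlation over the 5 libraries with expression was 0.84, above the 95th percentile of 10000 random sets matched on level (0.22, p = 0.0001 by permutation, the smallest they can give). In the set of 12 genes over 8 libraries it was 0.16, against 0.12 (permutation p = 0.02, adjusted over both sets 0.0002 and 0.02). The random sets were matched on level only, not on a shared absence. A shared source may account for the set of 11 genes. For the set of 12 genes the low correlation decides little, because a source present in similar amount in the 8 libraries would also give little shared variation. For the 12 genes, a treatment effect in 2 of the 5 miR-101a libraries cannot be told apart from such a source, because no other label separates those 2 libraries. The highest count for any other of the 45 pairs of libraries was 1 gene, which does not decide between them. Sequence differences between animals or reads shared between gene copies were not tested without a genome.

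Among the 100 splits fitted of 126 possible, the most calls came from the treatment grouping with miR-101a replicate 4 and scrambled replicate 1 exchanged. First-component scores were -32.57 to -5.16 in the libraries with most of the miR-101a group, against 12.61 to 18.42 in the other 5. The split thus parts the libraries along that component of the same data, so its count is no separate evidence of a structure. The split gave 803 edgeR genes, 770 of them lower in the libraries with most of the miR-101a group. The genes lower there were longer, with a median length of 4335 bases against 2691 over all genes tested, but with the length trend between libraries removed the split still gave 701 genes, 651 of them among the 803, and the median log2 difference of the 770 moved from -0.61 (SD 0.62) to -0.57, which argues against length as the whole cause. An exchange of the labels of these 2 libraries cannot be told apart from a difference unrelated to the treatment. As many as 20.6% of all splits lie as near to the treatment grouping as this one. That share is the same for every split 1 exchange away, whatever the data, so it does not bear on a label exchange. A treatment effect that did not take place in miR-101a replicate 4, with scrambled replicate 1 low for another reason, and differences in dissection, RNA quality or library batch also stay open and were not tested.

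In the deposited RPKM table the ratio of RPKM to count for a gene varied between libraries in a way their own totals did not explain. With totals taken in turn down the genes, as a vector recycled along a matrix column would give, the implied gene length had a median coefficient of variation of 1.7e-05 over the 10 libraries, against 0.144 with own totals, which is consistent with a slip in the order of division. The resulting errors had an SD of 0.202 on the log2 scale and reached 1.38-fold. Fold changes from the deposited values and from recomputed RPKM correlated across 18051 genes with r = 0.983, although genes are not independent replicates, and had opposite signs in 2350 genes (13%). Among these, of 956 genes at an unadjusted p below 0.05 with own totals and 312 with the deposited values, 250 were shared.

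As many as 15 DESeq2 genes came from 17 of 50 splits of the 10 libraries, the real one included, with up to 1074 in another split, so chance cannot be excluded for them. The edgeR count of 0 is reached by 100 of 100 splits by definition, so it tests nothing; another split gave up to 803. At an unadjusted p below 0.05, 40 of 100 splits gave at least 935 genes, with up to 2491, so chance is not excluded for that count.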
